A study of Mus musculus with 3 samples.

How the data were processed

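RNA was profiled in 3 samples of bone marrow cells that carried Sca-1 and lacked lineage markers, one from wild type C57BL/6J mice and one from each of 2 transgenic lines, Line 6 and Line 3, that carry a KDM1A construct named with the Ly6a (Sca-1) gene. Mice were 10 weeks old, per the labels. Total RNA was extracted with Trizol, amplified with the Ovation Pico WTA System, labelled with biotin from 3 ug of RNA and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The number of mice behind each sample and their sex are not given in the sources used here.

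The deposited values are intensities, one per probe set and array, on a linear scale. The summary method, the scaling and the software are not given in the sources used here. The values themselves show a prior scaling by the authors, because the mean intensity after trimming 2% from each end was 497 on all 3 arrays. Intensities ran from 0.0188 to 25535, with medians of 96.2 in wild type, 116 in Line 6 and 99.0 in Line 3. No detection calls came with the values, so a low intensity could not be told from background, and 22.5% to 24.4% of the probe sets on each array lay below 16.

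Each of the 45037 probe sets was paired with genes through the platform annotation, in which 34945 had 1 gene symbol, 932 had several and 9160 were not listed. Entrez identifiers of 34741 of those with 1 symbol matched the gene table used here (assembly GRCm38.p6), and 204 kept the annotation's own symbol. No probe set was paired with Ly6a in that annotation, so Ly6a is not reported here. No genomic coordinates are printed because the sources name no build.

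Intensities were transformed as log2(intensity + 16), so that differences of dim genes are understated on this scale. A gene was represented by its probe set with the highest mean over the 3 arrays, and it was kept when at least 1 array showed it at or above that array's median, which left 10864 of 18193 genes. Differences are line minus wild type, or Line 3 minus Line 6, on the log2 scale. With 1 array per genotype there is no replicate check of any difference, no standard error and no p-value for the main results. A gene was counted as higher or lower at a difference of 2-fold or more. The spread of Line 3 minus Line 6 over all genes (SD 0.38) is given as the only measure of how far 2 arrays of transgenic cells differed, and it holds biological differences between the lines as well as noise. The number of arrays limits the precision of every value.

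The design was fixed before the data were examined: the comparisons, the 2-fold limit, the filter, 40 gene lists and the rule for naming genes. The text names Kdm1a, the first 12 genes in each direction among those past 2-fold in both lines, ranked by the smaller of the 2 absolute differences, the first 5 per direction for genes past 2-fold in 1 line and within 1.2-fold in the other, the first 5 per direction between the lines, up to 4 members per gene list with the largest mean difference, and sex-linked genes. Gene models and accession-like symbols were counted but not named. Some further genes are named outside this rule, among them S100a8, S100a9, Ccl4, Il18 and Csf1. A list's median difference was placed among 10000 random lists of the same size, drawn with replacement and matched on mean expression in 20 bins, and called when it lay below percentile 2.5 or above percentile 97.5 in both lines. Such percentiles describe these arrays, and genes of a list are not independent of one another. 38 of the 40 lists had at least 5 measured members. A list with fewer than 5 in an alternative setting got no call there, so a call could also end for want of members. The Hoxa, stem cell and Notch lists were chosen knowing that the published study of these mice dealt with stem cell self-renewal, HoxA genes and T-cell leukaemia, so they are not independent evidence.

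Both lines were set against the same wild type array, so their differences share its chance values. Unchanged lines were simulated 100 times against a shared array with noise taken from Line 3 minus Line 6. The procedure was also tested on simulated data of both lines against wild type with 10864 genes, 200 of them changed: genes seeded at 2.5 on the log2 scale were all recovered in both directions, those seeded at 1.5 were recovered in 88.0% of cases when higher and in 80.0% when lower, and 38 of 10664 unchanged genes passed.

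Alternatives were quantile normalization, centring each array on its median, cyclic loess, no filter, a filter at percentile 75, the median of all probe sets of a gene, only probe sets with the plain _at suffix, pseudocounts of 1 and 64, limits of 1.5-fold and 3-fold, and a limma fit that took the lines as 2 samples of 1 transgenic group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.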

Results

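Gene expression was measured on 3 arrays of bone marrow cells that carried Sca-1 and lacked lineage markers, a fraction enriched for haematopoietic stem and progenitor cells. One array held cells of wild type C57BL/6J mice, one held cells of transgenic Line 6 and one held cells of transgenic Line 3. Each genotype had 1 array, so no difference below has a replicate error or a p-value of its own. A limma fit that pooled the lines is given as an alternative, and differences are given for both lines separately. All differences are on the log2(intensity + 16) scale and cover 10864 genes. Over all probe sets, the median intensity was 96.2 in wild type, 116 in Line 6 and 99.0 in Line 3.

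Kdm1a, the mouse gene for the histone demethylase LSD1, was higher by less than 2-fold in the transgenic cells. Its brighter probe set read 2104 in wild type, 2575 in Line 6 and 2979 in Line 3, differences of 0.29 and 0.50, and the Line 6 difference was 0.05 after centring on array medians. The dimmer probe set read 916, 911 and 1482, a difference of -0.01 in Line 6 and 0.69 in Line 3. Whether these mouse probe sets detect the transgene is not given in the sources used here, so they measure the endogenous transcript with an unknown share of the transgene. Among 19 measured genes of LSD1 corepressor complexes and partners, none differed by 2-fold in either line. Their median differences were 0.09 in both lines, turning to -0.15 in Line 6 after centring on array medians, at percentiles 73.5 and 43.7 of matched random lists, and the largest mean difference was that of Gfi1b, a zinc finger repressor that recruits LSD1, at 0.50 and 0.61.

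The first question was which genes differed from wild type in both transgenic lines. As groups, stem cell genes were higher in both lines and neutrophil genes were lower, while monocyte and macrophage markers went both ways. Cd5l, a protein secreted by tissue macrophages, was 9.86-fold higher in Line 6 and 11.7-fold higher in Line 3, and Il1b, the interleukin 1 beta gene, was 6.34-fold lower and 15.0-fold lower. In total 147 genes were at least 2-fold higher in both lines and 225 were at least 2-fold lower, while 1 gene passed the limit in opposite directions. Xist was higher and the Y-linked gene Eif2s3y lower in both lines on the same arrays, with values given at the end.

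The 12 leading genes among the 147 were headed by Cd5l. They included Fcna (ficolin A, 2.63 in Line 6 and 3.30 in Line 3), Mrc1 (the mannose receptor, 1.94 and 2.41), C1qb (a complement C1q chain, 1.78 and 2.05) and the lectin gene Cd209f (2.20 and 2.32). Igf1, encoding insulin-like growth factor 1, was higher by 2.66 and 2.86. Angpt1, the angiopoietin 1 gene, was higher by 1.76 and 1.96. Fgfbp3 (2.54 and 2.52), Rpusd3 (2.14 and 2.74), Maged1 (1.96 and 1.81), Serpinb9 (a granzyme B inhibitor, 1.77 and 1.85) and Iigp1 (an interferon-inducible GTPase, 1.93 and 1.85) completed the 12. In 83 of the 147 genes the wild type intensity lay below its array's median, where the fold depends most on the pseudocount. Over all 147 genes, 75 of the other probe sets above the filter, 83 in number, ran in the same direction in both lines, and dimmer probe sets were not counted.

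The 12 leading genes among the 225 lower ones were headed by Vcan, the proteoglycan versican, which read 1233 in wild type, 106 in Line 6 and 75.4 in Line 3. Crispld2 was lower (-2.96 in Line 6 and -3.86 in Line 3), as were the acute phase gene Orm1 (-2.94 and -3.28), Olfml2b (-2.80 and -3.09), the decoy receptor gene Il1r2 (-2.77 and -3.49), Il1b (-2.66 and -3.91) and the neutrophil chemokine gene Cxcl2 (-4.75 and -2.66). Inhba, an activin subunit gene, differed by -2.51 and -3.04, and Asprv1 by -2.37 and -4.06. Tcl1b3 (-2.46 and -2.42), Acvrl1 (-2.78 and -2.35) and Cldn1 (-2.28 and -2.33) completed the 12. Of the 94 other probe sets of the 225 genes that passed the filter, 92 ran in the same direction in both lines, and dimmer ones were not counted.

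**Figure D1:**
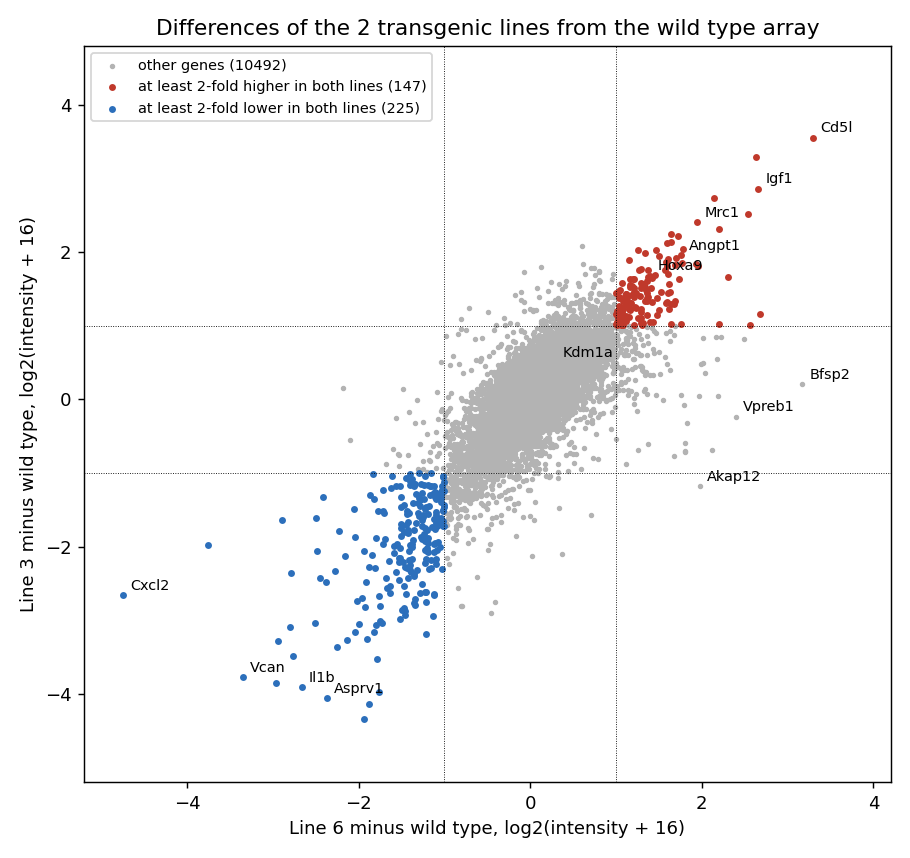
Each point is 1 of 10864 genes, with the difference of Line 6 from wild type on the x axis and that of Line 3 on the y axis, both in log2(intensity + 16) units, and dotted lines mark 2-fold. The 147 red genes were at least 2-fold higher in both lines and the 225 blue genes at least 2-fold lower, with Cd5l and Cxcl2 at the ends, and Kdm1a lay inside the limits.

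The wild type array stood apart more than either line did. It differed by 2-fold or more, in a single direction, from both other arrays at 372 genes, against 58 for the Line 6 array and 135 for the Line 3 array. Across genes, the differences of the 2 lines correlated with a Pearson r of 0.77, where unchanged lines simulated against a shared array gave 0.50, and their covariance was 0.22 against a simulated 0.07. Such simulations gave a median of 21 genes higher and 20 lower in both lines. Independent lists of the observed sizes would share 9.96 higher and 11.7 lower genes. The single wild type array could not be split, so part of the excess over either value may come from that array.

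The balance of the 2 directions moved with the scaling, the filter and the pseudocount. Of all genes past 2-fold in both lines, 39.5% were higher on the deposited scale, 26.0% after quantile normalization, 23.8% after cyclic loess and 19.0% after centring on array medians. The share was 16.9% with the filter at percentile 75 and 23.8% with a pseudocount of 64. The count of higher genes was 89, 85 and 76 under these 3 scalings. Of the 225 lower genes, 218 remained after quantile normalization and 223 after cyclic loess. All remained under centring, as they had to, because centring lowers both lines' differences from wild type. When limma took the lines as 2 samples of 1 group, 0 genes passed an adjusted p of 0.05 in either direction, with 973 higher and 759 lower at an unadjusted p under 0.05.

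Stem cell genes were higher in both lines as a group, on arrays where neutrophil markers were lower (medians -0.86 and -1.47). Of 37 genes of a haematopoietic stem cell list, 26 were measured. Among these, 11 were at least 2-fold higher in both lines, none was 2-fold lower in both and 15 did not pass in both. Genes dim in wild type, such as Procr (32.3) and Mecom (69.6), passed the filter only through the lines. The filter therefore favoured higher genes in this count. The median differences of the 26 genes were 0.80 in Line 6 and 1.07 in Line 3. Both lay above all 10000 matched random lists, and the list was also called without a filter. Examples are Procr, the endothelial protein C receptor used to mark stem cells (1.60 and 2.12), Mecom, a transcription factor gene of stem cells (1.69 and 1.82), Angpt1 and Hoxa9 (1.40 and 1.68). Of 13 listed Hoxa genes and cofactors, 6 were measured. Hoxa9, Hoxa5 (1.16 and 1.56) and Meis1 (1.03 and 1.11) were at least 2-fold higher in both lines and 3 did not pass in both. Hoxa5 passed the filter only through Line 3, at 128. Below the filter, on their brighter probe sets, Hoxa2 (0.78 and -0.30) and Hoxa11 (0.05 and -0.36) were lower in Line 3 than in wild type, and Hoxa4 and Hoxa10 were higher. The medians of the 6 measured genes were 0.83 and 1.11, at percentiles 99.85 and 99.97. The second Hoxa9 probe set gave 1.46 and 1.38. Both lists were chosen with knowledge of the published study and are not independent evidence. In Line 6, Hoxa5 and Meis1 lay below 2-fold under each of the 3 other scalings. The Hoxa list could not be called with the median of all probe sets or under the filter at percentile 75, because fewer than 5 members were measured there. Endothelial markers, which overlap with stem cell genes, were also higher, with 14 of 25 listed genes measured. Of the 14, 5 were past 2-fold higher in both lines, with Emcn at 1.37 and 1.67 and Stab2 at 1.61 and 1.23. Emcn and Stab2 were dim in wild type (26.4 and 84.2) and likewise passed the filter only through 1 or both lines. Of the others, 1 was lower (Aplnr, -1.15 and -2.30), and 8 did not pass in both. The endothelial list also had fewer than 5 measured members under the filter at percentile 75, so it could not be called there.

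Neutrophil genes were lower in both lines. All 19 measured neutrophil markers had lower intensities in both lines, and 8 were at least 2-fold lower in both. The median difference was -0.86 in Line 6 and -1.47 in Line 3, below all 10000 random lists in each case. Itgb2l, an integrin of neutrophils, differed by -1.92 and -2.82, and Mmp8, the neutrophil collagenase, by -1.28 and -2.63. The calprotectin genes S100a8 and S100a9 were the brightest of the list, near the top of the intensity scale, and differed by -0.18 and -0.45 and by -0.04 and -0.25. Among 17 measured genes of granulocyte-monocyte progenitors, 2 were 2-fold lower in both lines, Csf3r (the G-CSF receptor, -1.35 and -1.77) and Hp (haptoglobin, -1.10 and -1.36), and none was higher.

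Macrophage genes split into opposite directions, with 10 of 21 markers above 0 and 11 below 0 in both lines. Of the 21 monocyte and macrophage markers, 6 were at least 2-fold higher in both lines, 1 was lower and 14 did not pass in both. Mrc1, C1qb and C1qc (1.72 and 2.22) were among the higher ones, and Cd14, the lipopolysaccharide co-receptor gene, was 5.67-fold lower in Line 6 and 3.05-fold lower in Line 3. The list medians were -0.08 and -0.13 and were not called.

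Immediate early genes were lower in both lines, on arrays where neutrophil markers were lower too (medians -0.86 and -1.47). Of 27 immediate early genes, 3 were at least 2-fold lower in both lines and none was higher, with medians of -0.69 in Line 6 and -0.32 in Line 3 at percentiles 0 and 0.01. The list's median was 0.40 higher in Line 3 than in Line 6, above all random lists. Atf3 (-2.42 and -1.33), Klf2 (-1.31 and -1.41) and Egr3 (-1.41 and -1.10) were the 3. Of 22 genes of NF-kB signalling and inflammatory cytokines, 5 were lower in both lines. Among them were Cxcl2, Il1b (also on the neutrophil list), the prostaglandin synthase gene Ptgs2 (-3.75 and -1.98) and Tnf (-1.07 and -1.65). In Line 3, 4 others were at least 2-fold higher: Il6 (1.24), Ccl4 (1.19), Il18 (1.17) and Csf1 (1.03), which lay inside 2-fold under each of the 3 other scalings. The list's medians of -0.34 in Line 6 and -0.07 in Line 3 were not called (percentiles 0 and 4.98), nor was its difference between the lines (percentile 93.2).

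Genes of lymphoid priming were higher in both lines. Of 18 measured genes of lymphoid priming, 3 were at least 2-fold higher in both lines: Dntt (terminal transferase, 1.47 in Line 6 and 1.15 in Line 3), Rag2 (2.20 and 1.02) and Blnk (1.76 and 1.03), while 15 did not pass in both. The medians were 0.72 and 0.66, above all random lists, and the call ended under the filter at percentile 75. In Line 3, Rag2 and Blnk lay below 2-fold under each of the 3 other scalings, and Dntt did with the median of probe sets and with plain _at probe sets. B cell markers had a median of 1.44 in Line 6, above all random lists, and 0.33 in Line 3, at percentile 90.2. In Line 6, 10 of the 17 markers were at least 2-fold higher, and in Line 3 none was.

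The second question was how the lines differed from each other. 77 genes were at least 2-fold higher in Line 3 than in Line 6 and 172 were lower, with no test of these differences because each line had 1 array. The SD of this difference over all genes was 0.38, against 0.48 for Line 6 and 0.60 for Line 3 set against wild type. The share of higher genes was 30.9% on the deposited scale and 57.9% after centring on array medians, while quantile normalization (42.3%) and cyclic loess (41.6%) left it on the lower side.

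Akap12 (-3.16) and Bfsp2 (-2.97) were the leading genes lower in Line 3 than in Line 6, followed by Pax5, Vpreb1 and Cplx2. Pax5, the B lineage commitment factor, read 128 in wild type, 610 in Line 6 and 73.4 in Line 3. Vpreb1, a surrogate light chain gene, read 616, 3303 and 521. Cplx2 read 79.1, 315 and 42.6. As a list, B cell markers differed between Line 3 and Line 6 by a median of -1.19, below all random lists. On the other side, Cxcl2 (2.09), the interleukin 6 gene Il6 (1.95), Gna14 (1.90), the peptide transporter gene Slc15a2 (1.80) and Ptgs2 (1.78) were higher in Line 3 than in Line 6.

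Mast cell and basophil genes were higher in Line 3, with a median of 1.13 (percentile 100). The Line 6 median was 0.26 (percentile 99.3) and 0.028 after centring on array medians, and the call in both lines ended after quantile normalization and cyclic loess. Of 12 markers, 8 were at least 2-fold higher in Line 3 than in wild type and none was in Line 6. The 8 include genes that are also on other lists, among them Gata2 (1.05 in Line 3) and Csf1 (1.03). Csf1 lay inside 2-fold under each of the 3 other scalings. Cpa3, a mast cell carboxypeptidase gene, differed by 0.21 in Line 6 and 1.47 in Line 3, and Ms4a2, the beta chain of the IgE receptor, read 1351 in wild type, 1752 in Line 6 and 3857 in Line 3. The list median was 0.76 higher in Line 3 than in Line 6, above all random lists. Neutrophil markers were lower still in Line 3 than in Line 6 (median -0.61, below all random lists).

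Among genes past 2-fold in 1 line and within 1.2-fold of wild type in the other, 25 were higher and 8 lower in Line 6, and 28 were higher and 32 lower in Line 3. The leading ones in Line 6 were Bfsp2 (3.17), Vpreb1 (2.39), Vpreb3 (2.19), Rsph9 (1.97) and Myl4 (1.79) on the higher side, and Egr2 (-1.56), Egr1 (-1.48), Slc25a29 (-1.41), Trib3 (-1.32) and Slc66a1 (-1.04) on the lower side. Myl4 was 0.48 in Line 6 with the median of probe sets. Slc25a29 was -1.40 in Line 3 and -0.90 in Line 6 with a pseudocount of 1, and -1.02 in Line 3 with the median of probe sets. In Line 3 they were Epcam (1.80), Slc15a2 (1.73), Csrp3 (1.59), the steroid side-chain cleavage gene Cyp11a1 (1.52) and Cpa3 (1.47) on the higher side, and Sowaha (-1.86), Crtac1 (-1.64), Wnt8b (-1.60), Chadl (-1.58) and Ccdc187 (2.84-fold lower) on the lower side. Over the settings the Line 6 difference of Epcam ran from -0.61 to 0.15, so it did not always stay within 1.2-fold.

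**Figure D2:**
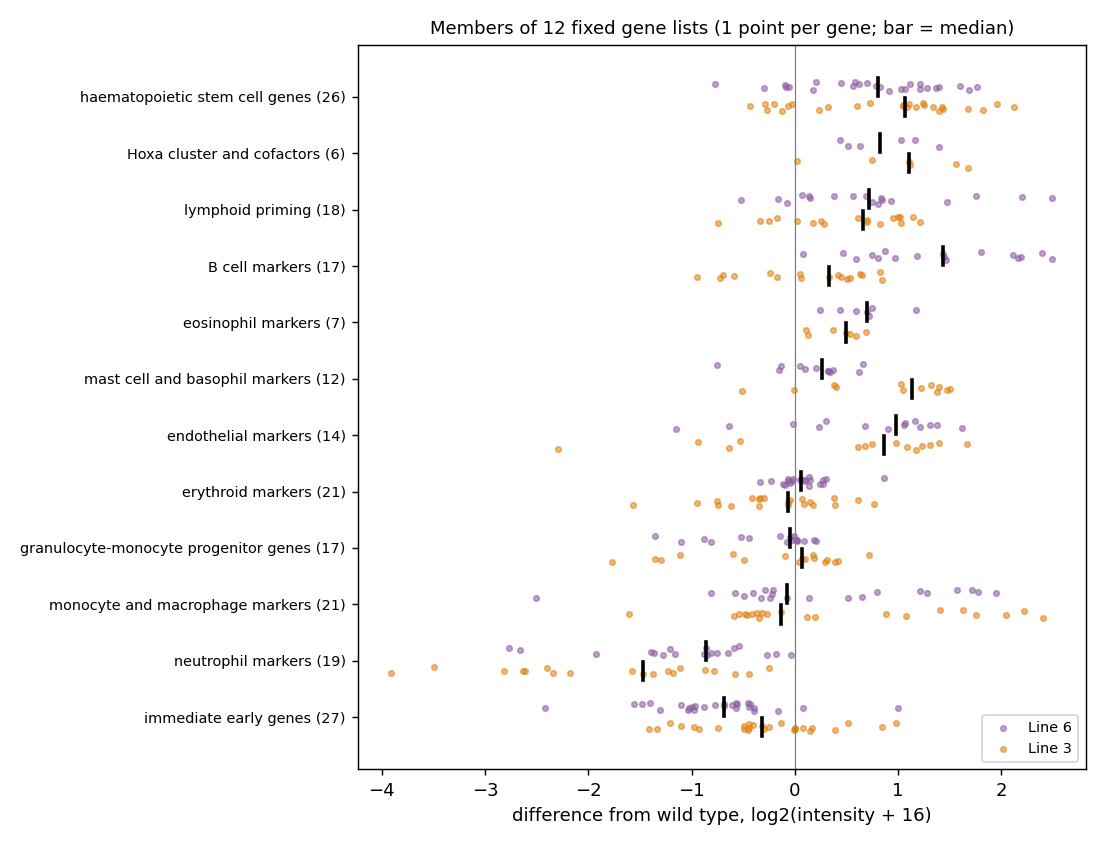
Each point is 1 measured gene of 12 fixed lists, placed by its difference from wild type on the x axis in log2(intensity + 16) units, in violet for Line 6 and orange for Line 3, with a black bar at the list's median and the number of genes in brackets. Stem cell genes lay mostly above 0 and neutrophil markers below 0 in both lines, and B cell markers lay higher in Line 6 (median 1.44) than in Line 3 (median 0.33).

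Sex-linked genes differed between wild type and both lines. Xist, the RNA of the inactive X chromosome, was higher on all 3 probe sets, by 1.17 to 2.16 in Line 6 and by 0.91 to 2.01 in Line 3. Eif2s3y, a Y-linked gene, was lower on both probe sets, by -1.24 and -1.33 in Line 6 and by -1.16 and -1.78 in Line 3. Kdm5d (-0.71 and -0.50) and Uty (-0.27 and -0.11) lay below wild type by less than 2-fold on their brightest probe sets. A further Kdm5d probe set gave -0.30 in Line 6 and -0.82 in Line 3, and another gave 0.04 and -0.07. The brightest probe sets of Xist and Eif2s3y read 2729 and 2325 in wild type, 6152 and 978 in Line 6, and 5155 and 1031 in Line 3.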

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

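Akap12, a kinase anchoring protein gene, was the 1 gene past 2-fold in opposite directions in the lines. It read 309 in wild type, 1264 in Line 6 and 127 in Line 3, so that Line 3 lay -3.16 from Line 6 on the log2 scale. The difference between the lines was not tested, because each line had 1 array. With a pseudocount of 64 the Line 3 difference of Akap12 from wild type was -0.96, inside the 2-fold limit.

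Probe sets that the annotation pairs with no gene were outside the report's comparisons. Of 2962 such probe sets that passed the filter, 78 were at least 2-fold higher in both lines than in wild type and 35 were at least 2-fold lower. Their genes are unnamed here.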

How the results depend on the processing

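No paired analysis was possible because each genotype had 1 array. Counts of genes past the limit moved with most settings, in the order higher in both lines, lower in both lines, higher in Line 6, lower in Line 6, higher in Line 3, lower in Line 3, higher in Line 3 than Line 6 and lower in Line 3 than Line 6. The deposited scale gave 147, 225, 279, 262, 388, 484, 77 and 172. Without a filter they were 272, 344, 679, 584, 692, 877, 276 and 557. With the filter at percentile 75 they were 30, 147, 60, 158, 112, 301, 23 and 70, with 6868 genes measured. That filter kept 30 of the 147 genes higher in both lines and 147 of the 225 lower ones. At 1.5-fold they were 675, 587, 1007, 753, 1636, 1116, 472 and 568, and at 3-fold 23, 53, 63, 68, 59, 193, 14 and 39. With a pseudocount of 64, the counts that moved by over 1.5 times were 51 higher in both lines, 125 higher in Line 6, 193 higher in Line 3, and 33 higher and 87 lower in Line 3 than in Line 6. Quantile normalization gave 89 genes higher in both lines and 178 higher in Line 6, and cyclic loess gave 85 and 171. Centring on array medians gave 76 higher in both lines, 144 higher and 468 lower in Line 6, and 151 higher and 110 lower in Line 3 than in Line 6. That centring moved the median of all genes from 0.06 to -0.17 in Line 6 and from 0.12 to 0.09 in Line 3. In Line 6, 34.0% of the genes past the limit were higher after quantile normalization, 32.3% after loess and 23.5% after centring, against 51.6% as deposited. Between the lines the share of higher genes was 42.3% after quantile normalization and 41.6% after loess. The limma fit of the lines as 1 group called 0 genes higher and 0 lower, with a smallest adjusted p of 0.0545 and 1 residual degree of freedom, and it assumes that the lone wild type array varies like the lines. Of 15 called gene lists on the deposited scale, 5 were called in all 9 settings of scaling, filter, probe set and pseudocount: stem cell genes, neutrophil markers, eosinophil markers, immediate early genes and haematopoietic transcription factors. Centring, 1 of the 9, is no check of a call, because it moves a list and its random lists alike. The filter at percentile 75 left 9 called lists, and lists with fewer than 5 measured members there could not be called. Centring turned the Line 6 medians of 3 called lists, cytosolic ribosomal proteins (-0.12), haematopoietic transcription factors (-0.018) and heat shock genes (-0.082), because it lowers all Line 6 values alike. Zap70, higher by 1.05 and 1.11 on its brightest probe set, reversed to -0.19 in Line 6 and -0.18 in Line 3 both with the median of probe sets and with plain _at probe sets. Among genes named here that were past 2-fold, with a pseudocount of 64 Aplnr, Emcn, Hoxa5, Meis1, Mertk, Slc25a29, Slc66a1, Spic, Tnf, Trib3 and Zap70 lay inside 2-fold in Line 6, and Akap12, Blnk, Ccdc187, Csf1, Egr3, Gna14, Hoxa5, Il18, Il6, Meis1, Rag2, Stab2 and Zap70 did in Line 3. Zap70 lay inside 2-fold in Line 6 under each of the 3 other scalings, and the brightest Xist probe set did after centring. The cause was not tested for the other changes. The correlation between the lines ran from 0.68 without a filter to 0.82 with the filter at percentile 75. Of the 147 higher genes, 83 lay below the wild type array's median intensity.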

Other observations

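The tests of explanations for the neutrophil, stem cell and sex-linked patterns were all chosen after the results were seen.

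Further genes of the 147 and 225 are named here after their values were seen, so they test no group. In Line 6, Mertk lay inside 2-fold under each of the 3 other scalings, and Siglec1 and Spic did with the median of probe sets. Siglec1 (1.52 in Line 6 and 1.46 in Line 3), the phagocytic receptor genes Axl (1.38 and 1.75) and Mertk (1.18 and 1.54), Spic (1.34 and 1.99), a transcription factor gene of iron-recycling macrophages, and Slco2b1 (1.41 and 1.52) were higher. The activating receptor genes Trem1 (-2.14 and -3.27) and Clec4e (-2.04 and -3.16), the stefin genes Stfa2l1 (-1.76 and -3.97) and Stfa3 (-1.75 and -3.01), Bst1 (-1.88 and -4.13) and Lrg1 (-1.99 and -3.05) were lower. Stefin genes belong to a family of similar copies, and whether their probe sets share signal was not checked.

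Cell cycle genes stayed within 2-fold of wild type. Of 34 measured genes of the G2 and M phases, none differed by 2-fold, with a range of -0.28 to 0.38 in Line 6 and -0.37 to 0.35 in Line 3, and of 33 S phase genes none did. The G2 and M list was lower in Line 3 than in Line 6 by a median of -0.098 (percentile 0.43). Erythroid markers had medians of 0.06 in Line 6 and -0.06 in Line 3, with -0.17 in Line 6 after centring on array medians, and were lower in Line 3 than in Line 6 (median -0.20, percentile 0.02). Alas2, the erythroid enzyme of haem synthesis, differed from wild type by -0.34 in Line 6 and -1.57 in Line 3. Of 16 genes of the Notch pathway and T-ALL oncogenes, 1 was 2-fold lower in both lines, Jag1 (-1.43 and -1.82), and the list, chosen with knowledge of the published study and so not independent evidence, was not called.

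Eosinophil markers were higher without reaching 2-fold in both lines (medians 0.70 and 0.49). Lists of NK cells (0.42 and 0.50) and group 2 innate lymphoid cells (0.76 and 0.79) were also called higher, and both calls ended under the filter at percentile 75, the NK call also with plain _at probe sets and the other with the median of probe sets. So were heat shock genes (0.15 and 0.24), cytosolic ribosomal proteins (0.11 and 0.17) and haematopoietic transcription factors (0.22 and 0.26), whose Line 6 medians turned negative after centring on array medians. The heat shock and ribosomal calls ended with plain _at probe sets, the former also with the median of probe sets and the latter after quantile normalization. Those of cell cycle inhibitors (-0.36 and -0.39) and apoptosis regulators (-0.17 and -0.25) were called lower, the first call ending without a filter and the second under the filter at percentile 75. Among 36 histone modifier genes, Kdm6b, an H3K27 demethylase gene, was the 1 past 2-fold in both lines (-1.51 and -1.69), and it lay at -0.54 and -0.78 with the median of probe sets and with plain _at probe sets. Jag1 was -0.96 in Line 6 with the median of probe sets.

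Neutrophil genes were lower in both lines. Scaling between the arrays is argued against by list medians of -0.86 and -1.46 after quantile normalization and -0.83 and -1.46 after cyclic loess. Centring on array medians is no check here, because it could only lower these medians. Among genes with a wild type intensity under 12768, 6 late genes lay lower than 3 early granule genes by a median of -0.48 in Line 6 (95% bootstrap interval over genes -1.91 to -0.18) and -1.32 in Line 3 (-2.40 to -0.79). This excludes no loss of neutrophils, because Fcnb and Hp, which with Pglyrp1 are the early genes, also belong to the list of granulocyte-monocyte progenitors, and other cells could hold up their level. Fewer residual neutrophils and a change of expression in the cells both stay open, with S100a8 at 25535 in wild type cells from a sort that would remove mature neutrophils.

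Stem cell genes were higher in both lines. A loss of neutrophils alone would raise every other cell type alike, but stem cell genes exceeded erythroid markers by a median of 0.74 in Line 6 (95% bootstrap interval over genes 0.44 to 1.10) and 1.13 in Line 3 (0.39 to 1.58). Of 16 lists of other cell types, 4 lay below the stem cell genes with intervals above 0 in both lines (erythroid, granulocyte-monocyte progenitor, megakaryocyte and stromal). The progenitor list keeps Fcnb and Hp, counted above as early neutrophil genes, so it does not speak against a loss of neutrophils alone. The other lists, lymphoid and endothelial ones among them, did not lie below in this way, so a change shared by stem cells and those types stays open. Scaling is argued against by a lowest median of 0.57 over 3 other scalings. A set of 10 stem cell genes, picked as not known from endothelium, had medians of 0.95 and 0.91. Whether these genes, Hoxa9, Kit and Nkx2-3 among them, are absent from endothelial cells was not checked, so they exclude no endothelial source. More endothelial cells, as part or all of the source, stay open. The 12 endothelial genes outside the stem cell list had medians of 0.79 and 0.71 (3 past 2-fold higher in both lines, 1 lower, 8 not past it). More stem cells, a higher expression per cell and a transgene effect stay open too. So does a joint loss of several residual cell types, which the erythroid contrast cannot test because it addresses neutrophils alone. The 3 single samples do not separate these.

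Xist was higher and Eif2s3y lower in both lines, while Kdm5d and Uty stayed within 2-fold. A larger share of female cells in the line samples is untested, because the count of 5 of 6 Y-linked probe sets above the filter that were lower in both lines restates the observation behind it. The sex of the animals is not given in the sources used here. Xist read 2729 in wild type, while Eif2s3y read 978 and 1031 and Kdm5d 389 and 452 in Lines 6 and 3. All lay well above the array medians of 96.2, 116 and 99.0. These values argue against a wild type sample of males only and line samples of females only. Whether the probe sets detect other transcripts was not checked. The share of each sex may still differ between samples, so sex share and transgene cannot be told apart.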
